A study of Mus musculus with 28 samples.

How the data were processed

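Gene expression was measured in liver of male mice with Affymetrix whole-genome mouse arrays, 1 array per animal, from total RNA. Per the labels, 16 arrays came from C57BL/6 mice at 6, 12, 18 and 24 months and 12 arrays from C3H mice on gestational day 19 (GD19), postnatal day 32 (PND32) and postnatal day 67 (PND67). The labels name 4 mice in each of the 7 groups and say that the C3H mice belong to a study described earlier. Per the labels' protocols, fetal pups were killed by decapitation and older mice with carbon dioxide. Neonatal animals that the protocols mention were not analysed here.

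The deposited values are probe set intensities on a linear scale, for 45101 probe sets on 28 arrays. The scanner software and the probe summary are not given in the sources used here. The deposited intensities were not on a common scale between arrays. Mean intensity per array ran from 92.7 to 295.3, and 14.1% to 21.1% of the values on each array lay below 0. The planned analysis had allowed for both cases and required quantile normalization for values of this kind. The table carried no detection calls, so the bound of background was set per strain at the 95th percentile of the sizes of the values below 0, which came to 52.6 for C57BL/6 and 22.1 for C3H. A gene at or below this bound on every array of a group is described as not well above background there. Its fold is then given as "at least", from the bright group's mean against, per dim array, the higher of the bound and the measured value. Apart from the ranks of the brightest genes, no level was compared between different probe sets, and no 2 arrays held identical values.

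Probe sets were named through the platform annotation. Of the probe sets other than 64 controls, which were left out, 34945 carried 1 gene symbol, 932 several and 9160 none. The gene identifier of 34741 of the first kind matched the mouse reference gene table and that of 204 did not, and 0 symbols were changed. Each gene was represented by the probe set with exactly 1 symbol and the highest mean over the 28 arrays, which gave 18193 genes. H19, Mup20, Gsta1 and Ddx3y had no probe set with that symbol alone.

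Arrays were quantile normalized within each strain, values below 0 were set to 0, and log2(value + 16) was taken. Changes are therefore on the log2(value + 16) scale, which understates the change of dim genes. Each strain was fitted apart with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 1 coefficient per age group, two-sided), with data.table (version 1.17.8) for tables and matplotlib 3.10.9 under Python 3.11.15 for plots. P-values were adjusted by Benjamini-Hochberg over all 18193 genes, with 0.05 as the threshold, and changes are given as log2 with the standard error of limma's fit. An age trend in C57BL/6 was fitted as log2 per month over the 4 ages.

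Before the data were examined, 39 gene lists were fixed, with 1492 entries of which 1264 were measured. The 4 lists of xenobiotic metabolizing enzymes and transporters (XME) were cytochrome P450s of phase I, other phase I enzymes, phase II enzymes and transporters. Together they held 341 symbols, 274 of them measured. The remaining lists covered regulators of these genes, hepatic functions, stress responses and the cell types a liver sample could hold. Lists were tested with camera at a preset correlation of 0.01, again with a correlation estimated per list, and with fry, which asks whether a list's genes move on balance 1 way. The rule for named genes, also fixed in advance, took the 8 largest rises and 8 largest falls among called genes whose groups did not overlap, the called member with the largest change from each list (the 2 largest from each XME list), and a fixed set of hepatic and sex-linked genes whether called or not. Predicted transcripts were skipped among the largest changes. Genes named outside the rule were chosen after their values were seen, and the text says so.

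The alternatives fixed in advance were array median scaling, quantile normalization of all arrays together, scaling to a list of plasma protein genes for GD19, pseudocounts of 1 and 64, a filter on dim genes, other choices of probe set, array weights, other variance settings, other samples in the fit, a minimum of 1.5-fold, a replicate block for C3H, and leaving out each animal. Added after seeing the data were trimmed mean scaling, covariates for array brightness and for the 3 prime to 5 prime ratio of Gapdh control probe sets, and fits without GD19 replicate 4 (also with plasma protein scaling) or replicates 2 and 4. The labels give no array date or batch.

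The fit was tested on simulated data with known changes in a small part of the same 18193 genes. The changed genes were drawn only from those above the median level of all genes. The simulated spread came from all arrays of the strain, which for C3H included GD19 replicate 4. The simulated GD19 comparison with PND67 held 67 genes changed 4-fold, 66 changed 2-fold and 67 changed 1.5-fold. These are far fewer than the 6272 genes called in the real comparison. The rates therefore describe the fit in that setting, and not the normalization or the choice of probe sets. For GD19 against PND67, 79.1% of genes changed 4-fold and 51.5% of genes changed 2-fold were recovered, with 9.17% false calls among all calls. For 24 against 6 months, 92.0% and 91.3% were recovered, with 7.34% false calls. Over all comparisons the share of false calls ran from 7.34% to 11.4% (12 against 6 months), which is above the threshold of 0.05. The number of arrays, 4 per group, limits the precision.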

Results

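The series followed hepatic expression of xenobiotic metabolizing enzymes (XME), the enzymes and transporters that oxidize, conjugate and export foreign compounds, through the life of the male mouse. Fetal (GD19), juvenile (PND32) and young adult (PND67) livers came from C3H mice, and livers of 6, 12, 18 and 24 months from C57BL/6 mice, with 4 animals per group. Because the strains came from different studies and were normalized apart, ages were compared within a strain. Within every C57BL/6 group and within the C3H PND32 and PND67 groups, each array's mean correlation with the other arrays of its group was at least 0.975. Mean intensity per array was 106 to 161 at PND32 and PND67, 92.7 to 151 at GD19 and 173 to 295.3 in C57BL/6.

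The Y-linked genes Eif2s3y, Kdm5d and Uty were above background on every array, while Xist, transcribed from the inactive X chromosome of females, was not well above background in any group. GD19 replicate 4 stood apart from the other arrays, with a mean correlation of 0.842 to its group against 0.920 to 0.927 for the other 3. It carried the lung surfactant transcript Sftpc at a log2 value of 13.29, against 4.29 to 4.86 on the other GD19 arrays, and the club cell transcript Scgb1a1 at 12.61. Transcripts of intestine stood out on GD19 replicate 2, where Guca2a was at 9.67 and Cdh17 at 8.97, against at most 4.23 and 4.39 on the other GD19 arrays, and neither was above background on any PND32 or PND67 array. Fabp2 (11.97) and Apoa4 (11.56), against at most 7.54 and 6.44 on the other GD19 arrays, were also high on that array, but at PND32 and PND67 they had means of 10.08 and 10.05 and of 10.06 and 10.33 and so are liver transcripts as well. Sftpc, Scgb1a1, Guca2a, Cdh17, Fabp2 and Apoa4 were chosen after their values were seen.

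**Figure D1:**
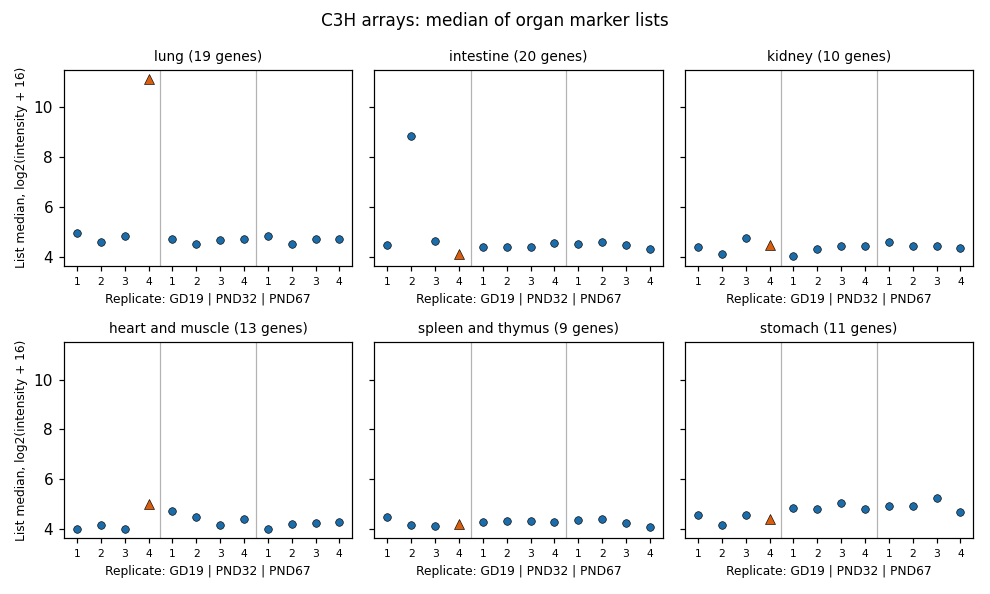
Median log2(intensity + 16) of 6 organ marker lists on each C3H array, with replicates on the x axis grouped by stage. The triangle is GD19 replicate 4, whose lung median is 11.15, against 4.59 to 4.97 on the other GD19 arrays, and the high point of the intestine panel is GD19 replicate 2 (8.85).

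The comparison of GD19 with PND67 asked how fetal liver differs from young adult liver. Genes of fetal growth and blood formation were among the largest rises at GD19, and XME genes among the largest falls. Igf2, the imprinted fetal growth factor, was at least 114-fold higher at GD19 (7.99 ± 0.39 log2, adjusted p = 3.83e-07, n = 4 per group), and Afp, the fetal plasma protein alpha-fetoprotein, rose by 7.63 ± 0.26 (adjusted p = 2.49e-08, with 1 of 4 PND67 arrays above background). In the opposite direction, the major urinary protein gene Mup3 was at least 138-fold lower (-8.36 ± 0.06, adjusted p = 1.3e-13). Cyp1a2, the caffeine-oxidizing cytochrome P450, was at least 127-fold lower (-8.01 ± 0.13, adjusted p = 8.6e-11). Of 18193 genes tested, 6272 changed, 2982 upward and 3290 downward, and 448 of these were not well above background in either group.

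Among the XME genes, 162 of 274 changed, 20 upward and 142 downward, and 176 changed with p-values adjusted over the list alone. Without GD19 replicate 4, 33 rose and 149 fell. In the P450 list, 34 of 55 members fell and 4 rose (7 rose without replicate 4). Cyp2c29 was at least 146-fold lower (-7.86 ± 0.11, adjusted p = 5.64e-11) and Cyp2c50 at least 104-fold lower (-7.46 ± 0.15). Cyp3a11, the main adult CYP3A enzyme, fell by 3.63 ± 0.57 (adjusted p = 0.00076) and Cyp2e1, which oxidizes ethanol, by 2.09 ± 0.68 (adjusted p = 0.0368). The call of Cyp2e1 was lost with the 2 groups alone (adjusted p = 0.105) and with the replicate block (adjusted p = 0.0515). It was also lost without any 1 of the 4 PND67 animals (0.0693 to 0.0749), while its adjusted p was 8.31e-06 without GD19 replicate 4. Cyp3a16, a fetal form of CYP3A, went the other way and was at least 5.21-fold higher at GD19 (3.57 ± 0.69, adjusted p = 0.00262, above background on 3 of 4 GD19 arrays). The 3 other P450s that rose were Cyp4a14, Cyp2j13 and Cyp4x1, chosen after their values were seen, all with a PND67 mean that was not well above background. Without GD19 replicate 4, the values were -2.89 ± 0.05 for Cyp3a11, -1.21 ± 0.09 for Cyp2e1, 4.46 ± 0.06 for Cyp3a16 and -1.98 ± 0.13 for Cyp4a12a, which had fallen by 2.87 ± 0.70 with it.

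Other phase I enzymes fell in 43 of 75 cases and rose in 5, with the carboxylesterase Ces1f at -6.41 ± 0.12 (above background on 1 of 4 GD19 arrays) and the alcohol dehydrogenase Adh4 at least 27.1-fold lower. In phase II, 41 of 63 members fell and 4 rose (7 without GD19 replicate 4). The sulfotransferase Sult2a8 was at least 90.4-fold lower (-7.17 ± 0.17) and Mettl7b fell by 6.82 ± 0.29 (above background on 1 of 4 GD19 arrays), while the microsomal glutathione transferase Mgst3 rose by 3.40 ± 0.36. Transporters were more mixed, with 24 of 81 lower and 7 higher (12 higher without replicate 4). Of these, the organic anion transporter Slco1a1 was at least 42.7-fold lower (-6.67 ± 0.11), and Slc22a30 at least 30.3-fold lower, whereas the efflux transporter Abcc1 rose from a PND67 mean that was not well above background. Mgst3 and Abcc1 were chosen after their values were seen. Among 37 regulators of XME genes, 13 fell and 3 rose, and 21 fell without replicate 4. The nuclear receptor genes Nr1i3 (CAR) and Nr1i2 (PXR) fell by 3.47 ± 0.38 and 1.34 ± 0.26 (above background on 2 and 3 of 4 GD19 arrays), and Nr0b2 (SHP) was at least 9.53-fold lower, while Ahr had a change of 0.47 ± 0.35 (adjusted p = 0.345).

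**Figure D2:**
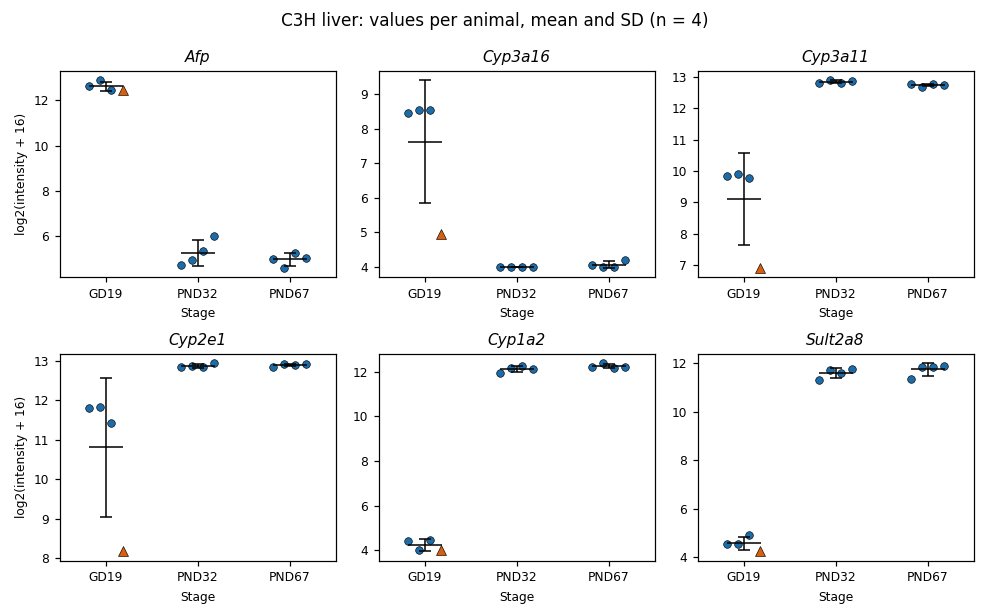
Log2(intensity + 16) of 6 genes in each C3H liver, by stage, with the mean and SD of 4 animals per group; the triangle is GD19 replicate 4. Afp and Cyp3a16 were higher at GD19, the other 4 genes were lower, and the triangle lies apart for Cyp3a16 (4.96), Cyp3a11 (6.90) and Cyp2e1 (8.17).

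The list of fetal and imprinted genes rose in 20 of 27 members and fell in 1, with Dlk1 at least 56.4-fold higher (6.65 ± 0.26, but 0.24 ± 0.18 and adjusted p = 0.358 without probe sets of the _s_at and _x_at kinds) and Cd24a up by 6.61 ± 0.28 (above background on 2 of 4 PND67 arrays). Cells of the blood lineages were represented by 33 of 40 erythroid genes that rose, among them Hemgn at least 30.5-fold higher, and 1 that fell. Granulocyte genes rose in 17 of 20 cases, with S100a8 up by 7.60 ± 0.58 and S100a9 by 7.47 ± 0.45 (above background on 2 and 1 of 4 PND67 arrays). The granule peptide gene Camp was at least 50.0-fold higher, 11 of 16 megakaryocyte genes rose with Ppbp at least 22.5-fold higher, and the embryonic globin gene Hbb-y was at least 3.05-fold higher. Proliferation genes rose in 43 of 49 cases, with the mitotic gene Ube2c up by 5.23 ± 0.61 (above background on 1 of 4 PND67 arrays). Without GD19 replicate 4, Hemgn, Ppbp and Asns (2.80 with it) rose by 7.00, 6.19 and 3.49.

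Of 25 male-biased genes 20 fell, including Hsd3b5 (at least 76.0-fold lower), and 0 rose. Bile acid genes fell in 17 of 26 cases, with Cyp7b1 at -7.20 ± 0.21 (above background on 1 of 4 GD19 arrays), although Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had a change of -2.20 ± 1.00 (adjusted p = 0.119), or -1.40 ± 0.89 without GD19 replicate 4 (adjusted p = 0.263). Urea cycle and amino acid genes fell in 21 of 26 cases, with tryptophan dioxygenase Tdo2 at -6.50 ± 0.29 (above background on 3 of 4 GD19 arrays). The acute phase gene Orm1 fell by 7.28 ± 0.24 (above background on 1 of 4 GD19 arrays) and the lipogenic regulator Thrsp was at least 71.3-fold lower. Alb, among the 18 brightest genes on every PND32 and PND67 array, had a change of 0.14 ± 0.07 (adjusted p = 0.163), and plasma protein genes as a list had a median change of -0.55 with GD19 replicate 4 and -0.16 without it. Perivenous hepatocyte genes fell in 15 of 22 cases and periportal genes in 13 of 21. Cells other than hepatocytes and blood cells were represented by stellate genes, of which 14 of 37 rose and 2 fell. Among them was Col5a2 at 3.04 ± 0.66 (2.36 without replicate 4, above background on 1 of 4 PND67 arrays). Endothelial genes were mixed, with 4 of 29 higher and 4 lower (7 and 6 without replicate 4). The endothelial gene Lyve1 rose by 3.22 ± 0.43 (2.83 without replicate 4).

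By camera at the preset correlation, 24 of the 39 lists changed, 9 upward and 15 downward, and fry called 26 lists. With a correlation estimated per list, the fetal and imprinted list remained past the threshold (adjusted p = 0.00181). The other lists did not, with adjusted p = 0.223 with an estimated correlation for P450s, other phase I, phase II, XME regulators and perivenous genes, and adjusted p = 0.379 with an estimated correlation for transporters, urea cycle and stellate genes. It was 0.263 for erythroid, granulocyte, megakaryocyte and proliferation genes, 0.343 for bile acid and periportal genes, 0.0789 for male-biased genes and 0.713 for plasma proteins. Without GD19 replicate 4, 14 lists passed with the estimated correlation, among them all 4 XME lists (adjusted p = 0.0237 for P450s, phase II and transporters and 0.0137 for other phase I). Proliferation genes did not (adjusted p = 0.0631 with an estimated correlation).

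The direction of the whole set depended on the scaling. Scaling each array to the plasma protein list moved the values of the genes by a median of 0.68 log2, and 3480 genes then rose and 819 fell. XME genes still mostly fell, with 98 lower and 33 higher. The median level of that list was 10.03 on GD19 replicate 4, 12.08 to 12.28 on the other GD19 arrays and 12.58 to 12.62 at PND32 and PND67. With replicate 4 left out, a setting added after seeing the data, the same scaling moved the values by a median of 0.26, and 5531 genes rose and 2097 fell, 47 and 130 of them XME genes. Trimmed mean scaling moved them by a median of 0.13 and gave 3949 higher and 2664 lower, and array median scaling gave 2187 higher and 4541 lower. Alb had a negative value under array median scaling (-0.80), and Nnt, a mitochondrial gene included as a label check that fell by 0.58 ± 0.17, had a value of 0.37 under plasma protein scaling. Nnt did not pass without GD19 replicate 1, 3 or 4 or PND67 replicate 1 or 4 (adjusted p = 0.0527 to 0.0679).

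Set against PND32, the juvenile stage, GD19 gave a similar picture. S100a8 (7.68 ± 0.58) and Afp (7.35 ± 0.26, adjusted p = 3.52e-08) rose (above background on 1 and 2 of 4 PND32 arrays), and Mup3 was at least 136-fold, Cyp1a2 at least 117-fold and Cyp2c29 at least 149-fold lower at GD19 than at PND32 (adjusted p = 1.33e-13, 1.06e-10 and 5.43e-11). In all, 6022 genes changed, 2866 upward and 3156 downward. XME genes changed in 165 of 274 cases, 19 upward and 146 downward, and in 177 with p-values adjusted over the list alone. Without GD19 replicate 4, 31 rose and 152 fell. P450s fell in 36 and rose in 3 of 55 cases, other phase I enzymes fell in 44 and rose in 5 of 75, phase II enzymes fell in 40 and rose in 4 of 63, and transporters fell in 26 and rose in 7 of 81. Without replicate 4, 7 P450s, 7 phase II enzymes and 11 transporters rose. Cyp3a16 was again at least 5.21-fold higher and Cyp3a11 lower (-3.73 ± 0.57, or -3.00 ± 0.05 without replicate 4). Camera called 24 lists, of which the fetal and imprinted list kept its call (adjusted p = 0.00215 with an estimated correlation). For P450s, other phase I and phase II this gave adjusted p = 0.232 with an estimated correlation and for transporters 0.419. By fry, 24 lists were called. Scaled to the plasma proteins, 3306 genes rose and 786 fell (5413 and 2051 with replicate 4 left out). Trimmed mean scaling gave 3836 and 2588, and array median scaling 2052 and 4278.

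Juvenile liver at PND32 was also set against young adult liver at PND67. Cyp1a2 differed by -0.11 ± 0.13 log2, Cyp3a11 by 0.10 ± 0.57, Cyp2e1 by -0.02 ± 0.68, Sult2a8 by -0.15 ± 0.17 and Cyp7a1 by -1.31 ± 1.00 (adjusted p = 1 for each, n = 4 per group). These standard errors came from a spread shared with GD19, replicate 4 included. Without that array they were 0.04 for Cyp3a11 and 0.09 for Cyp2e1, with adjusted p = 1 for both, and by limma 0 genes passed, 549 had an unadjusted p under 0.05 and the lowest adjusted p was 0.661. Cyp3a11 and Cyp2e1 were among the 30 brightest of 18193 genes on every array of these stages, where quantile normalization leaves little room for a difference. Afp, at 5.26 ± 0.57 (SD) at PND32 and 4.98 ± 0.28 at PND67, differed by 0.28 ± 0.26. By limma, 0 of 18193 genes passed the threshold, 369 had an unadjusted p under 0.05, and the lowest adjusted p was 0.489. Of the 274 XME genes 3 had an unadjusted p under 0.05 (6 without GD19 replicate 4) and 0 passed when adjusted over the list alone. In the simulated version of this comparison 81.7% of genes changed 4-fold and 50.8% of genes changed 2-fold were recovered. Part of the changes of that size would thus be missed by the fit that includes GD19 replicate 4, whose spread the simulation used. Recovery without that array and among genes below the median level was not simulated.

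Camera at the preset correlation called 5 lists between PND32 and PND67. Proliferation genes had a positive value in 43 of 49 cases at the younger age (median 0.26) and stellate genes in 32 of 37 (median 0.28), and transcripts of pancreatic enzymes had a median of 0.51. The median level of the pancreatic transcripts was 6.93 on PND32 replicate 1, 4.43 to 4.61 on the other 3 PND32 arrays and 4.26 to 4.80 at PND67. The median was -0.43 for circadian clock genes and -0.12 for antigen presentation genes. For the clock list this was adjusted p = 0.851 with an estimated correlation and for the 4 other lists adjusted p = 0.995 with an estimated correlation, and fry called 0 lists.

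In C57BL/6 mice, the first step of ageing went from 6 to 12 months. Cyp3a11 differed by -0.05 ± 0.04 log2, Cyp1a2 by -0.09 ± 0.15, Cyp4a12a by -0.19 ± 0.14 and Cyp7a1 by 0.70 ± 0.43 (adjusted p = 0.847, 0.975, 0.85 and 0.816). Ces2b, chosen after its values were seen, differed by -0.93 ± 0.31 (adjusted p = 0.574). By limma, 0 genes passed the threshold at 12 against 6 months, while 1268 had an unadjusted p under 0.05 and the lowest adjusted p was 0.166. Of the XME genes 23 had an unadjusted p under 0.05, and 1 rose with p-values adjusted over the list alone. Leaving out 1 animal gave 0 to 2 genes, the 2 without 12 month replicate 6.

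Camera called 7 lists at 12 months. PPARalpha targets, genes of fatty acid oxidation, had a negative value in 30 of 34 cases (median -0.22). Pancreatic transcripts had a median of 0.32, with levels of 6.27 and 6.57 on 12 month replicates 13 and 17, 4.88 and 5.18 on replicates 3 and 6, and 4.87 to 5.26 at 6 months. The median was 0.17 for B and plasma cell genes, 0.17 for interferon response genes, 0.09 for cholesterol synthesis genes, 0.09 for acute phase genes and 0.05 for plasma protein genes. For PPARalpha targets, pancreas, plasma proteins and B cells this became adjusted p = 0.577 with an estimated correlation and for interferon, acute phase and cholesterol genes adjusted p = 0.952 with an estimated correlation.

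At 18 months, 20 genes were past the threshold. Ighm, the heavy chain of immunoglobulin M, was at least 20.02-fold higher than at 6 months (5.23 ± 0.80, adjusted p = 0.0402, n = 4 per group), and the hepatic secreted protein gene Fgl1 rose 2.65-fold (1.40 ± 0.21, adjusted p = 0.0402). Tmem176a and Tmem176b rose by 0.72 ± 0.11 and 0.64 ± 0.10, Itih4, an acute phase plasma protein, by 0.42 ± 0.06, and the RNA sensor Ddx58 by 0.51 ± 0.08. Mtf1, the metal-responsive transcription factor, fell by 0.61 ± 0.08 (adjusted p = 0.022) and the translation factor Eif4a2 by 0.23 ± 0.03. Of the 20, 15 rose and 5 fell, and 3 of them, among which were Limk1 and Zfp583, were not well above background at either age. Dmrta1 and Pamr1 were above background on 1 of 4 arrays at 18 months and not well above background at 6 months.

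No XME gene passed over all genes at 18 months (0 by limma, 45 at an unadjusted p under 0.05), and 14 passed when adjusted over the list alone, 3 upward and 11 downward. The count of 20 fell to 1 without 18 month replicate 4, and leaving out each other animal gave 3 to 15. Of 15 named genes that were called, 1 kept its call whichever animal was left out. Camera called 16 lists at the preset correlation. Cholesterol synthesis genes had a positive value in 20 of 20 cases (median 0.46) and interferon response genes in 33 of 35 (median 0.50), acute phase genes had a median of 0.20 and PPARalpha targets were negative in 33 of 34 cases (median -0.25). For cholesterol, PPARalpha and acute phase genes this became adjusted p = 0.238 with an estimated correlation, for interferon genes adjusted p = 0.409 with an estimated correlation, and for B cells 0.21.

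At 24 months, several immunoglobulin and acute phase genes were higher than at 6 months, and several XME genes were lower. Ighm was at least 25.3-fold higher (5.57 ± 0.80, adjusted p = 0.00799, n = 4 per group), the immunoglobulin kappa gene Igkv8-30 rose by 3.18 ± 0.58, and lipocalin 2 (Lcn2), an iron-binding acute phase protein, was at least 5.78-fold higher (2.84 ± 0.47, adjusted p = 0.0175). The carboxylesterase Ces2b fell by 2.37 ± 0.31 (adjusted p = 0.00513, above background on 1 of 4 arrays at 24 months). In total, 233 genes changed, 112 upward and 121 downward, all with non-overlapping groups, and 23 of them were not well above background at either age. Other large rises were those of Noct, a deadenylase with a daily rhythm (2.80 ± 0.45, 6.98-fold), the thyroxine-binding globulin Serpina7 (1.79 ± 0.32), S100a8 (at least 2.37-fold) and Mmd2 (at least 1.87-fold). Large falls were those of the coactivator Ppargc1b (-1.73 ± 0.35, above background on 3 of 4 arrays at 24 months), Gpcpd1 (-1.44 ± 0.30) and Rcan2 (-1.20 ± 0.22, above background on 1 of 4 arrays at 24 months).

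Of the 274 XME genes 13 changed at 24 months, 10 downward and 3 upward, and 42 changed when adjusted over the list alone, 11 upward and 31 downward. Besides Ces2b, the glucuronosyltransferases Ugt2b38 (-1.39 ± 0.26, adjusted p = 0.0267) and Ugt2b1 (-0.35 ± 0.06, adjusted p = 0.0172) fell. Among P450s, the male-biased fatty acid hydroxylase Cyp4a12a fell by 0.73 ± 0.14 (1.66-fold, adjusted p = 0.0304) and Cyp2j6 by 0.64 ± 0.10 (adjusted p = 0.0103). The aldo-keto reductase Akr1e1 fell by 0.43 ± 0.08. The falls of Abcg2, Mettl7a1, Ces2a and Akr1c12, given to complete the 10, lay between 0.27 and 0.41. The potassium channel subunit Abcc9, a member of the ABC transporter family, rose by 0.70 ± 0.11 (adjusted p = 0.0133) and the monocarboxylate transporter Slc16a1 by 0.69 ± 0.14. Slc22a27 was called but not well above background at either age. Abcg2, Mettl7a1, Ces2a, Akr1c12 and Slc16a1 were chosen after their values were seen. Cyp1a2 had a value of -0.53 ± 0.15 (adjusted p = 0.1). Cyp2e1 had a value of -0.03 ± 0.03 and Cyp3a11 of -0.00 ± 0.04 (adjusted p = 0.727 and 1), but both were among the 31 brightest of 18193 genes on every C57BL/6 array, where quantile normalization leaves little room for a change. Cyp2b9, a female-biased P450, had a value of 1.36 ± 0.47 (adjusted p = 0.162, above background on 3 of 4 arrays at 24 months and 0 of 4 at 6 months).

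**Figure D3:**
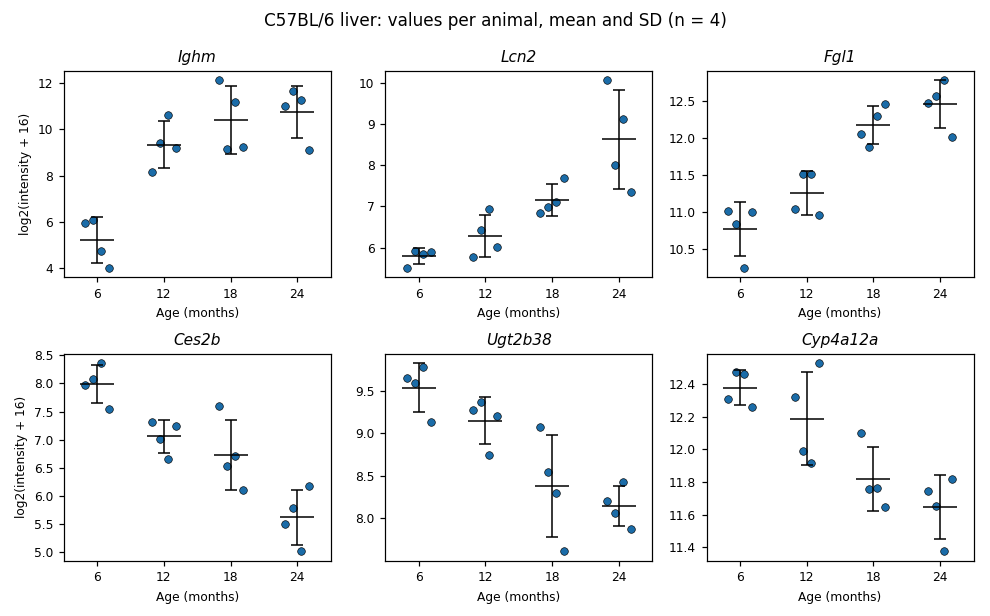
Log2(intensity + 16) of 6 genes in each C57BL/6 liver against age in months, with the mean and SD of 4 animals per group. Ighm, Lcn2 and Fgl1 were higher at 24 than at 6 months and Ces2b, Ugt2b38 and Cyp4a12a lower, with no overlap between these ages.

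At 24 months, genes of Kupffer cells and macrophages had a positive value in 29 of 31 cases (median 0.92), with 1 member called, Cd9 (0.90 ± 0.12, adjusted p = 0.00513). Interferon response genes were positive in 33 of 35 cases (median 0.65, Ddx58 called at 0.48 ± 0.08), antigen presentation genes in 24 of 24 (median 0.39, Tapbp called at 0.64 ± 0.14) and B and plasma cell genes in 20 of 25 (median 0.42, Ighm called). For Kupffer, interferon and antigen presentation genes this was adjusted p = 0.365 with an estimated correlation and for B cells 0.329. T and NK cell genes had a median of 0.37 with 0 of 36 called (adjusted p = 0.462 with an estimated correlation). Of 28 acute phase genes 6 rose, Lcn2, Fgl1, Orm2, Apcs, Itih4 and Hp, and 0 fell. Fgl1 rose by 1.69 and Itih4 by 0.49 ± 0.06. The fatty acid synthase gene Fasn rose by 0.74 ± 0.16. Genes of oxidative phosphorylation were negative in 65 of 66 cases by small amounts (median -0.14), and 6 fell, with Ndufb3 at -0.42 ± 0.09. Male-biased genes fell in 4 of 25 cases and 0 rose, among them the growth hormone receptor gene Ghr (-0.22 ± 0.05). The urea cycle gene Otc fell by 0.30 ± 0.06. Orm2, Apcs, Hp and, at 24 months, Fgl1 were chosen after their values were seen.

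Camera called 23 lists at 24 months, 16 upward and 7 downward, and none held with an estimated correlation. For acute phase genes this gave adjusted p = 0.259 with an estimated correlation, and for male-biased, phase II and oxidative phosphorylation genes adjusted p = 0.365 with an estimated correlation. Other phase I enzymes were at 0.462. By fry, acute phase (adjusted p = 0.00479), oxidative phosphorylation and B cell genes (0.028 each), and Kupffer, male-biased and phase II genes (0.038 each) passed.

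The arrays of 24 months differed from those of 6 months in brightness and in a measure of RNA quality. The 24 month animals were also numbered apart from the other C57BL/6 animals, and what the numbers stand for is not given. Mean intensity was 283.6 ± 9.12 (SD, n = 4) at 24 months and 240.7 ± 19.1 at 6 months (exact permutation p = 0.0286, two-sided, adjusted p = 0.0429 over 3 measures). The log2 ratio of 3 prime to 5 prime Gapdh probe sets was -0.26 ± 0.02 (SD) against -0.13 ± 0.04 (exact permutation p = 0.0286, adjusted p = 0.0429). The same ratio for Actb did not pass, at 0.53 ± 0.06 (SD) against 0.72 ± 0.10 (exact permutation p = 0.0571, adjusted p = 0.0571). With the brightness as a covariate 96 genes were called, 5 of them XME genes, and 63 of the 96 were among the 233. With the Gapdh ratio 0 were called, while the median size of the change in the 233 genes was 0.51 with it and 0.49 without, all 233 kept their sign, and the median standard error went from 0.0937 to 0.149. The count of 233 was 42 without 24 month replicate 33 and 552 without replicate 34, and that of XME genes was 4 without 6 month replicate 16 and 26 without 24 month replicate 34. Of 36 named genes called at 24 months, 8 kept their call whichever animal was left out.

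Across the 4 ages, 280 genes had a linear trend, 151 rising and 129 falling. Fgl1 rose by 0.10 ± 0.01 log2 per month (adjusted p = 0.00228), which came to 1.80 over the 18 months, Lcn2 by 0.16 ± 0.02 and Ighm by 0.30 ± 0.05. Ces2b fell by 0.12 ± 0.02 per month (adjusted p = 0.00343), a change of -2.23 over the 18 months. XME genes had a trend in 14 of 274 cases, 4 rising and 10 falling, and in 39 with p-values adjusted over the list alone. Cyp4a12a fell by 0.77 over the 18 months (adjusted p = 0.0104) and Cyp2j6 by 0.61 (adjusted p = 0.00473). With the Gapdh ratio as a covariate 1 gene was called. The count was 80 without 24 month replicate 33, and that of XME genes was 8 without replicate 29 and 22 without replicate 34. Without the 24 month animals 18 genes and 0 XME genes had a trend. Camera called 23 lists for the trend, and none held with an estimated correlation, the lowest being acute phase genes (adjusted p = 0.0813 with an estimated correlation).

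Of the 20 genes called at 18 months, 16 were called in the same direction at 24 months, 13 upward and 3 downward, among them Ighm, Fgl1, Tmem176a, Tmem176b, Itih4, Ddx58, Mtf1 and Eif4a2. Both comparisons used the same 6 month animals. In 100 simulations all 16 C57BL/6 arrays, the 6 month ones included, were redrawn without change around the 6 month means. Both simulated comparisons shared the redrawn 6 month arrays. On average 0.01 called genes were shared, but at most 1 gene was called per comparison. In a test added after the result was seen, the 20 and 233 genes of lowest p in each simulation shared 6.81 in direction on average and at most 12, so part of the 16 may come from the shared animals. Independent lists of these sizes would share 0.0923 upward and 0.0333 downward. When the 6 month animals were divided between the comparisons in the 6 possible ways, 0 to 3 genes were shared, but the fits then called only 0 to 25 genes at 18 months and 0 to 97 at 24 months, and in 2 of the divisions 1 comparison called 0. Where 25 and 41 genes were called 2 were shared, and where 14 and 53 were called 3 were shared, against 0.0284 and 0.0206 for independent lists.

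The genes called at 24 months were also set against those of GD19. Of genes called in both, 75 went the same way, 26 upward and 49 downward, where independent lists would share 18.4 and 21.9, and 28 went opposite ways, where independent lists would give 40.1. Cyp4a12a and Cyp2j6 were lower both at GD19 against PND67 and at 24 against 6 months, as were Akr1e1 and Ghr. Fgl1, in contrast, fell by 3.30 at GD19 and rose at 24 months. Its log2 values at GD19 were 7.61 to 9.08 on replicates 1 to 3 and 5.17 on replicate 4. Fgl1, Cyp2j6, Akr1e1 and Ghr were chosen here after their values were seen.

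**Figure D4:**
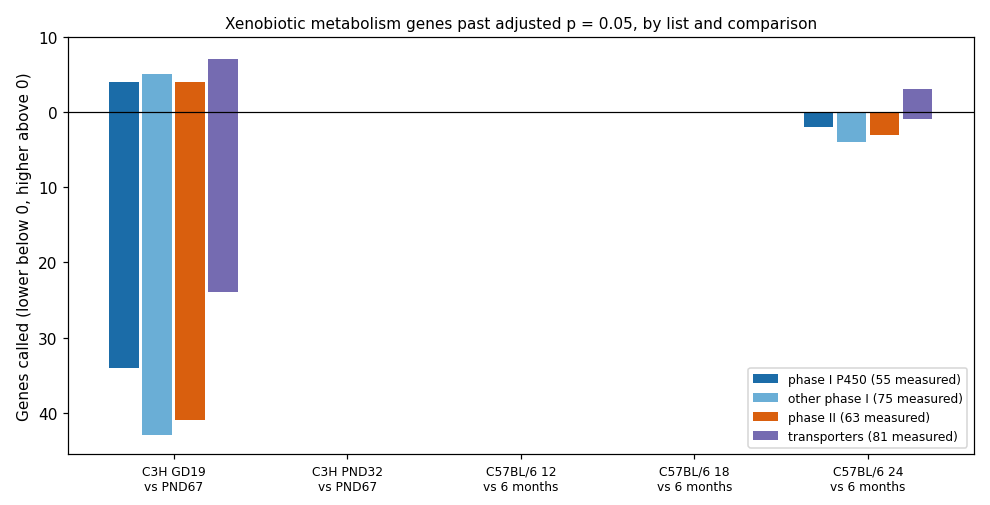
Number of genes past the threshold in each XME list, by comparison, with lower genes drawn below 0 and higher genes above. At GD19 34 P450s, 43 other phase I enzymes, 41 phase II enzymes and 24 transporters were lower, and PND32 against PND67 and 12 and 18 against 6 months have no bars.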

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

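Single animals far from the others of their group were found by Dixon's ratio, which chance exceeds in about 1 in 20 groups, and 27 of 302 groups of values of named genes and 1 of 35 groups of array measures exceeded it. The counts over other groupings of the samples were planned before the results were seen, and the other 8 tests in this part were chosen after the result was seen.

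The array of GD19 replicate 4 had a mean correlation of 0.842 with its group, against 0.920 to 0.927 for the other 3. It also lay apart for Igf2 (11.23), S100a9 (11.41), Cd24a (11.58), Hemgn (7.74), Ppbp (7.77), Gstm3 (4.84), Asns (7.21), Cyp2e1 (8.17), Cyp3a11 (6.90), Cyp3a16 (4.96), Cyp4a12a (5.95) and Ier3 (10.07), on the log2 scale. Only Ier3 was higher than on the other arrays. For lung tissue in the sample, the differences of 19 lung genes from their means on the other 3 arrays had a median of 5.42 log2, against at most 0.35 for the other organ lists that were measured, and this result fits. Against low RNA quality, the log2 ratio of 3 prime to 5 prime Gapdh was 0.00665, where the other GD19 arrays reached 0.235. Against lung RNA alone, 23 of 29 plasma protein genes lay at 8 times the background bound or more. That shows liver RNA in the sample but not its share. The hepatic genes Hnf4a, Abcb11 and Slc10a1 differed from their means on replicates 1 to 3 by -4.10, -3.75 and -3.49 log2. For Alb and Afp the differences were 0.11 and -0.21. Hnf4a, Abcb11 and Slc10a1 were chosen after their values were seen. How lung transcripts came into the sample stays open, and a biological cause was not tested.

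XME genes were lower at GD19, and a lower share of hepatocytes in fetal liver is a possible reason. Without replicate 4 and with each array scaled to the plasma protein genes below the top of the scale, 128 of the 142 lower genes were still called lower. Their median was -1.90, so most XME genes fell further than these plasma proteins did. The 10 plasma protein genes did not move together, with changes from -5.88 (Azgp1) to 0.50 (Itih3) and a median of -0.49 without replicate 4. They may therefore not follow the share of hepatocytes, and this test does not decide on that share. Without replicates 2 and 4, the arrays with lung or intestine transcripts, 137 were still called lower. Whether fetal hepatocytes make less of the plasma proteins themselves stays open.

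The genes called at 24 against 6 months came from arrays that were brighter and had another Gapdh ratio than those at 6 months. With brightness as a covariate, a median share of 0.983 of the change was left. Then 96 genes were called, 63 of them among the 233, and the standard error rose from 0.0937 to 0.110. Mean intensity did not overlap between these ages, at 227.1 to 269.0 at 6 months and 275.2 to 295.3 at 24 months. The correction therefore rests on the spread of brightness within age groups, where 12 month replicate 3 was the dimmest array (172.9). For that reason the share left does not decide on brightness as the source. With the Gapdh ratio the share was 0.973, but 0 genes were called and the standard error rose to 0.149, so RNA quality cannot be told from age here. For a lower share of hepatocytes, the 8 plasma protein genes below the top of the scale had a median change of 0.171. The 10 lower XME genes had a median of -0.42. All 8 had positive values, but only Itih4 (0.49, adjusted p = 0.00513), also an acute phase gene, was called by limma. Because acute phase genes rose at 24 months, plasma proteins may not follow the share of hepatocytes, so this test does not decide. The biological side, a change with age itself, stays open because age and array measures moved together.

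Each count was compared with the counts from every other division of the same 8 arrays into 4 and 4. At GD19 against PND67 the real division alone, 1 of 35, reached 6272 genes (highest other 4) and 162 XME genes (highest other 1). At GD19 against PND32 again 1 of 35 reached 6022 (highest other 5) and 165 (highest other 0). Divisions that mix the groups carry any difference between them in their spread, which lowers their counts. The gap to the other counts therefore does not measure chance, and 1 of 35 is the smallest share that 35 divisions can give. A real count of 0 is reached by every division, so 35 of 35 says nothing about chance for all genes and XME genes at PND32 against PND67 and at 12 against 6 months, or for XME genes at 18 against 6 months. At PND32 against PND67, 1 other division, PND67 replicate 1 with PND32 replicates 1 to 3, called 39 genes and 4 XME genes, which points to a structure of the samples that was not tested. At 12 against 6 months the highest other was 2 for all genes and 0 for XME genes. At 18 against 6 months 1 of 35 reached 20 genes (highest other 7), and the highest other for XME genes was 0. At 24 against 6 months 1 of 35 reached 233 genes (highest other 2) and 13 XME genes (highest other 0). Of 100 draws of the ages, 1 reached 280 genes with a trend (highest other 1) and 1 reached 14 XME genes (highest other 0).

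The remaining single animals are given as log2 values, with the other 3 of the group in brackets. In C3H they were Cyp2b10 in PND32 replicate 1, 5.55 (5.15 to 5.20), and Acaa1b in PND32 replicate 4, 12.03 (11.43 to 11.53). At PND67, replicate 1 lay apart for Sult2a8, 11.38 (11.85 to 11.90), Pck1, 10.9996 (11.96 to 12.13), Col5a2, 5.98 (4.69 to 4.86), and Cyp2b9, 6.93 (4.48 to 4.81), and replicate 4 for Cyp2c50, 11.88 (11.97 to 11.97), and Eif2s3y, 8.44 (at most 8.04). In C57BL/6 at 6 months, replicate 2 lay apart for Gpcpd1, 9.96 (10.81 to 10.93), Abcc9, 8.80 (8.74 to 8.75), and Ghr, 12.69 (12.59 to 12.61), and replicate 11 for Nr1i2, 8.42 (8.18 to 8.21). The others were Kdm5d at 12 months in replicate 13, 7.71 (7.16 to 7.24), Ahr at 18 months in replicate 4, 9.21 (9.64 to 9.66), and Abcc9 at 24 months in replicate 25, 9.70 (9.36 to 9.40).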

How the results depend on the processing

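Of the counts of genes, lists and shared calls, 192 kept within 1.5 times of their main value and 68 did not, apart from those that left out an animal. The 192 include comparisons without a called gene in either fit, such as most of those of PND32 against PND67. Leaving out 1 animal kept the count of genes within this range in 1 fit and moved it in 7, at 18 and again at 24 months. For the trend it was kept in 10 and moved in 6, and for GD19 against PND67 it was kept in all 8. The causes of the differences were not tested except where fewer samples or fewer genes explain them. Values of named genes were counted as unchanged in 4654 cases, lost a call in 438 and gained one in 44. In 5 cases they changed direction while called in either fit. Lists were counted as unchanged in 1053 cases, lost a call in 245, gained one in 27 and changed direction with both calls in 1. Genes and lists called in neither fit counted as unchanged even where their direction changed. The signal over background limits what can be said of dim genes, and 448 of the genes called at GD19 against PND67 were not well above background in either group. The scalings by trimmed mean and to the plasma proteins with GD19 replicate 4 left out, and the covariates, were chosen after seeing the data.

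At GD19, Alb had a value of -0.80 against PND67 and -0.63 against PND32 with array median scaling. With plasma protein scaling, Nnt had values of 0.37 and 0.23, Uty had a value of 0.0892 against PND32, and the oxidative phosphorylation list turned upward against PND32 (adjusted p = 0.00405). For PND32 against PND67, array weights gave 2 genes. For 12 against 6 months, a pseudocount of 1, the Gapdh covariate and the brightness covariate each gave 1 gene.

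For 18 against 6 months, the 20 genes became 4 with array median scaling, 3 with the mean of probe sets, 4 with the 2 groups alone, 13 with all 28 arrays in 1 fit (1 XME gene), 11 with a 1.5-fold minimum, 9 with trimmed mean scaling, 4 with the Gapdh and 8 with the brightness covariate. For 24 against 6 months, the 233 genes and 13 XME genes became 70 and 7 with array median scaling, 367 with dim genes left out (fewer genes tested), 635 and 29 with array weights, 2 and 0 with the 2 groups alone (fewer samples), 49 and 3 with all 28 arrays, 93 and 7 with a 1.5-fold minimum, 0 and 0 with the Gapdh and 96 and 5 with the brightness covariate, and trimmed mean scaling gave 24 XME genes. For the trend, 280 and 14 became 82 and 7 with array median scaling, 428 with dim genes left out, 664 and 31 with array weights, 18 and 0 without 24 months, 89 and 4 with all 28 arrays, 124 and 8 with a 1.5-fold minimum, 1 and 0 with the Gapdh and 144 with the brightness covariate, and trimmed mean scaling gave 22 XME genes.

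With an estimated correlation, camera called 1 list for GD19 against PND67 and 1 against PND32 (14 and 13 without replicate 4), and 0 for PND32 against PND67, for 12, 18 and 24 against 6 months and for the trend. Fry called 26 lists for GD19 against PND67 and 24 against PND32. It called 0 for PND32 against PND67 and for 12 and 18 months, 6 for 24 months and 8 for the trend. With the Gapdh covariate, camera at the preset correlation called 4 lists at 12 months and 15 at 24 months. The 16 genes shared by 18 and 24 months became 8 with a 1.5-fold minimum and 0, 2, 0, 0, 3 and 0 with the 6 month animals divided (1, 25, 0, 1, 14 and 5 genes called at 18 months and 97, 41, 31, 0, 53 and 15 at 24 months, so the low numbers do not show a loss of sharing), and the 75 shared by GD19 and 24 months became 22.

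Leaving out 1 animal gave 5268 to 7122 genes (XME 139 to 182) for GD19 against PND67, 5033 to 6833 (XME 139 to 183) against PND32, 0 to 0 for PND32 against PND67, 0 to 2 for 12 months, 1 to 15 for 18 months, 42 to 552 (XME 4 to 26) for 24 months and 80 to 415 (XME 8 to 22) for the trend. With the replicate block in C3H, 5964 genes (154 XME) changed at GD19 against PND67, 5737 (148 XME) against PND32 and 0 for PND32 against PND67. The replicate numbers gave 12 pairs with correlations of -0.117 to 0.183, 3 of them highest with their own number, so the numbers do not pair the samples.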

Other observations

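The clock genes named here were chosen after their values were seen, and 0 of the 22 on the clock list passed the threshold at 24 against 6 months. Dbp, a clock output transcription factor, had log2 values of 4.86 to 8.29 at 24 months and 8.11 to 11.50 at 6 months (difference -3.98 ± 1.27, adjusted p = 0.136, n = 4 per group), with means of 10.13, 9.33, 9.30 and 6.15 at 6, 12, 18 and 24 months. Nr1d1, a repressor of the clock, differed by -1.77 ± 0.66 (adjusted p = 0.194), Usp2 by -1.85 ± 0.89 (adjusted p = 0.31) and Per1 by -0.67 ± 0.33 (adjusted p = 0.317). The activators Arntl and Npas2 had values of 1.69 ± 0.66 (adjusted p = 0.215) and 1.58 ± 0.50 (adjusted p = 0.129). Noct, which is not on the clock list, passed (2.80 ± 0.45, adjusted p = 0.0146). At 18 months Dbp ran from 5.81 to 11.12, in the order of the animal numbers 4, 9, 14 and 19. Arntl ran the other way there, from 7.95 to 5.33. At 6 and 12 months the lower-numbered animals also had the lower Dbp values. The 24 month animals were numbered apart, from 25 to 34, and what the numbers stand for is not given. For these clock genes an effect of age cannot be told from one that goes with the animal numbers. All 24 month animals carry the separate numbers, so this limit applies to every gene called at 24 against 6 months, Noct included.

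On GD19 replicate 2, the differences of 20 intestine genes from their means on replicates 1 and 3 had a median of 2.37 log2, and 9 of the 20 lay more than 3 log2 above. Of these 9, 6 were not above background on any PND32 or PND67 array. The list median was 8.85 on replicate 2, and 4.50 and 4.63 on replicates 1 and 3. On GD19 replicate 4, the differences from the means of the other GD19 arrays had a median of -2.42 over erythroid genes and -1.87 over plasma protein genes.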
